A study of Homo sapiens with 2 samples.

How the data were processed

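Total RNA of MHCC97H control cells and of MHCC97H cells with GP73 knocked down was extracted with Trizol, per the labels' protocols, from cultures grown in medium with 10% fetal bovine serum. Per the same protocols, 100 ng of total RNA was made into biotin-labelled single-stranded cDNA by the Affymetrix whole-transcript method. Each condition was hybridised to 1 array, and the labels do not describe pooling. The series title also speaks of GP73 overexpression; such samples were not analysed here. The sequence used for the knockdown is not given in the sources used here.

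The deposited table held log2 signals, 1 value per row and array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the background correction, the normalisation between arrays, the summary of probes into rows, the log base and the genome build are not given in the sources used here. The log2 scale was taken from the values, which ran from 0.36 to 13.2 in the control array and from 0.33 to 13.3 in the knockdown array. The medians were 4.72 and 4.80, and the 95th percentiles 8.66 and 8.60, so the distributions were close but not identical. The scanner files, spot-level detection calls and probe-level data were not used here, so a floor on signal took the place of a detection test. The precision is limited by the number of arrays, 1 per group.

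Rows were named through the platform annotation of the array, which gave 1 gene symbol for 23784 of the 70523 rows, several for 1540 and none for 45199. Symbols were updated through the NCBI gene table of assembly GRCh38.p14, by gene identifier for 21497 rows, by symbol for 1977 and by a unique older symbol for 306, and 4 kept the name in the annotation. Genes are named only from rows with 1 symbol, and genomic positions are not printed because the build of the array annotation is not given. Genes without a row of their own were not analysed here. For 529 genes with several rows the row with the highest mean over the arrays stood for the gene, and none of the 15 genes with the highest and the 15 with the lowest difference had a second row. A gene counted as measured when its higher signal reached the 50th percentile of that quantity over all 22413 genes, a log2 signal of 5.84.

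With 1 array per group there was no test between conditions. The results are the log2 difference of each measured gene, the number of genes at least 2-fold higher or lower, and the median difference of 32 gene lists. Each list's median was ranked among 10000 random lists of the same size, drawn from measured genes in the same 10 bins of mean signal, and this percentile describes the 2 arrays only. These choices, the lists and the rule for named genes were fixed before the data were examined. The rule names GOLM1, the 15 measured genes with the highest and the 15 with the lowest difference, and up to 4 members of each list with the largest absolute difference; genes named outside it are marked as chosen after their values were seen. As a measure of error within an array, rows of the same gene were compared. Rows that shared both values with another row were left out, and 100 genes then had exactly 2 rows above the floor. The SD between the differences of the rows of 1 gene was 0.133, and 84 of the 100 pairs had the same sign. Whether the rows of a pair share probes was not checked, so this SD may be too small.

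The alternatives tried were median centring, quantile normalisation of the arrays, removal of a lowess trend of the difference over the mean, no floor and a floor at the 75th percentile, the mean over the rows of a gene, counting rows in place of genes, thresholds of 1.5-fold and 3-fold, a robust z of 4 against genes of similar signal in 20 bins, random lists not matched on signal, and the mean in place of the median of a list. Counts and random lists restricted to protein-coding genes were added after the data had been seen. No replicate could be left out. The procedures were tested on simulated data built from the 11207 measured genes with normal noise of the observed spread. Of 200 genes changed 2-fold 47.5% passed the 2-fold threshold, of genes changed 3-fold 98.5%, and of genes changed 1.5-fold 5.5%, with 2 unchanged genes passing each time. Of 87 simulated lists without a shift 2.3% lay outside the central 95%, and of lists shifted by 0.2 in every member 77.0%. The share recovered at 2-fold follows largely from setting the threshold at the simulated change. The noise had the same spread for every gene, a robust SD of 0.264, whereas that of the small nucleolar RNAs was 0.400. The 2 unchanged genes therefore do not estimate how many of the observed genes past 2-fold were unchanged. The noise was drawn separately for each gene, so these shares do not cover lists whose members vary together. The metallothionein, leukocyte and fibroblast lists, with few measured members, were not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.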

Results

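Gene expression was measured in MHCC97H, a human liver cancer cell line, after knockdown of GP73. GP73 is a membrane protein of the Golgi apparatus, encoded by GOLM1, whose level is known to be raised in liver disease and hepatocellular carcinoma. The series comprised 2 Affymetrix arrays, 1 of control cells, which the labels describe as expressing GP73 at a high level, and 1 of cells with GP73 knocked down. Each condition was therefore measured once, no replicate error exists for any value below, and no p-value was computed between the conditions. The stated purpose was to find which genes act with or downstream of GP73 in liver cancer cell growth. Each array gave 70523 log2 signals. The median signal was 4.72 in the control array and 4.80 in the knockdown array, and the signals of the arrays correlated across the measured genes with a Pearson r of 0.970, in which genes are not independent replicates. Of 22413 genes with a row of their own, 11207 reached a log2 signal of 5.84 in at least 1 array and are called measured here, 9920 of them protein-coding. Differences are log2 signals of the knockdown array minus the control array.

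The first question was whether the targeted transcript was lower in the array labelled as the knockdown. GOLM1, measured by transcript cluster TC09002894.hg.1, had a log2 signal of 9.13 in the control array and 7.46 in the knockdown array, a difference of -1.67, or 3.18-fold lower. It was rank 1 of the 11207 measured genes counted from the lowest difference in the signals as deposited. ADH1C was lower with quantile normalisation, at -1.66 against -1.60 for GOLM1, and with the trend over signal level removed, at -1.69 against -1.60. GOLM1 was represented by 1 row of the array, so no second row could be set beside it. The closest relative of GOLM1, GOLM2, had signals of 9.25 and 9.27; it was looked up after its values were seen. For scale, 100 genes had 2 rows of distinct value above the floor, and the SD between the differences of rows of 1 gene was 0.133. That SD covers measurement within an array, and not the variation between cultures, RNA preparations or hybridisations. It may be too small where the rows of a pair share probes, which was not checked.

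The main comparison asked which other genes differed between the GP73 knockdown and the control cells. Few genes differed strongly. In the knockdown array 18 of the 11207 measured genes were at least 2-fold higher and 15 at least 2-fold lower, and at a threshold of 1.5-fold the numbers were 121 and 174. Protein-coding genes made up 9 of the 18 and 8 of the 15, and the other genes past the threshold were mostly small nucleolar RNAs, microRNAs and pseudogenes. Over all measured genes the SD of the difference was 0.262, and its 1st and 99th percentiles were -0.64 and 0.60. No replicate shows how many genes 2 arrays of the same cells would place past the same thresholds.

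**Figure D1:**
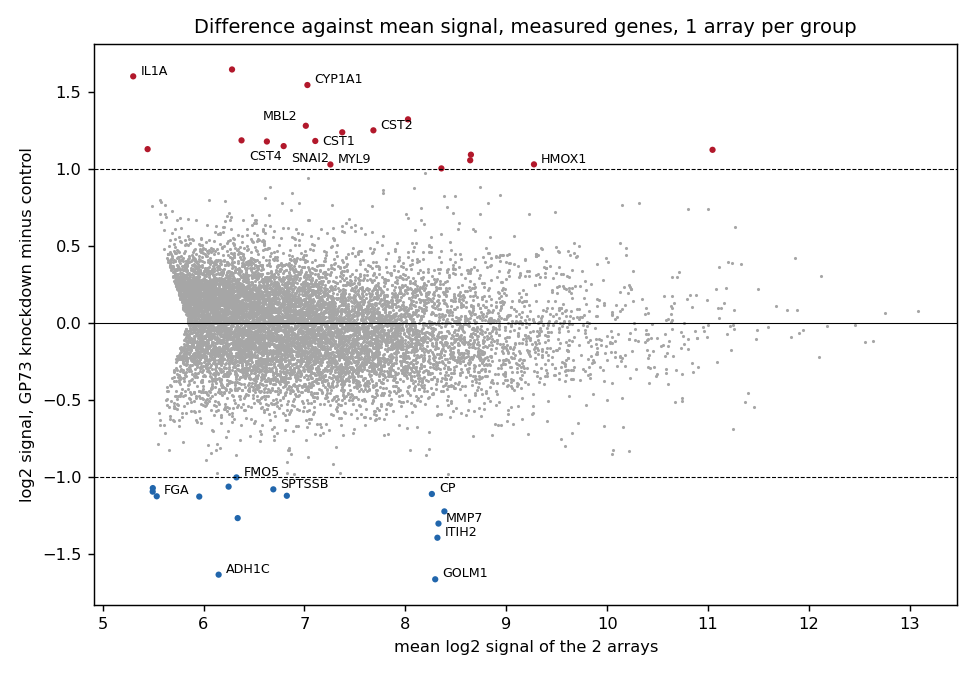
Each point is 1 of 11207 measured genes, placed by its mean log2 signal over the 2 arrays (x axis) and by its log2 signal in the GP73 knockdown array minus the control array (y axis); dashed lines mark a 2-fold difference, red and blue points lie past it, and those that are protein-coding are named. GOLM1 is the lowest point, at -1.67, and most genes lie between -0.64 and 0.60.

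Besides GOLM1, 7 protein-coding genes were among the 15 lower by most, and ITIH2, FGA and CP of these belong to the hepatocyte list described further on. ADH1C, an alcohol dehydrogenase, had log2 signals of 6.97 in the control and 5.33 in the knockdown array, the latter below the floor of 5.84. ITIH2, a heavy chain of the plasma inter-alpha-trypsin inhibitor family, was 2.63-fold lower, from 9.02 to 7.62. FGA, the fibrinogen alpha chain, went from 6.10 to 4.97, also below the floor, and CP, the copper-carrying plasma ferroxidase ceruloplasmin, was 2.16-fold lower, from 8.82 to 7.71. FMO5, a flavin-containing monooxygenase, went from 6.83 to 5.82, just below the floor. MMP7, the secreted protease matrilysin, was 2.47-fold lower, from 8.98 to 7.68. SPTSSB, a small subunit of the enzyme that begins sphingolipid synthesis, was 2.12-fold lower. The remaining 7 of the 15 genes lower by most were not protein-coding. They were the small nucleolar RNAs SNORD12C at -1.27, SNORD1A at -1.13 and SNORD12 at -1.12, the spliceosomal RNA RNU5D-1 at -1.23, the long noncoding RNA LOC286437 at -1.10, and the pseudogenes RNU7-35P at -1.07 and HNRNPA3P1 at -1.06. Of these, SNORD12C, SNORD1A, LOC286437, RNU7-35P and HNRNPA3P1 were below the floor in the knockdown array, so the size of their differences is uncertain.

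Of the 15 genes higher by most in the knockdown array, 7 were protein-coding. IL1A, the cytokine interleukin-1 alpha, had log2 signals of 4.50 in the control array, which is below the floor, and 6.10 in the knockdown array. CYP1A1, a xenobiotic-metabolising cytochrome P450, was 2.92-fold higher, from 6.26 to 7.80. MBL2, a plasma lectin that activates complement, was 2.43-fold higher, from 6.37 to 7.65. SNAI2, the transcriptional repressor Slug, which is linked to epithelial-mesenchymal transition, was 2.22-fold higher, from 6.22 to 7.37. The secreted cystatins CST2, CST1 and CST4 were 2.38-fold, 2.27-fold and 2.26-fold higher. These cystatin genes are close paralogs, and the split of signal between them is uncertain. The highest difference of any measured gene was that of the microRNA gene MIR222, at 1.65, from 5.46, which is below the floor, to 7.11. The other genes of the group were the microRNA genes MIR4449 at 1.32 and MIR4674 at 1.06, the small nucleolar RNAs SNORA14A at 1.24, SNORA23 at 1.12 and SNORD99 at 1.09, the antisense transcript PCNA-AS1 at 1.19, and the immunoglobulin segment IGHD2-21 at 1.13. PCNA-AS1 and IGHD2-21 were below the floor in the control array. PCNA, which PCNA-AS1 overlaps on the opposite strand and which was looked up after its value was seen, had a difference of -0.16.

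**Figure D2:**
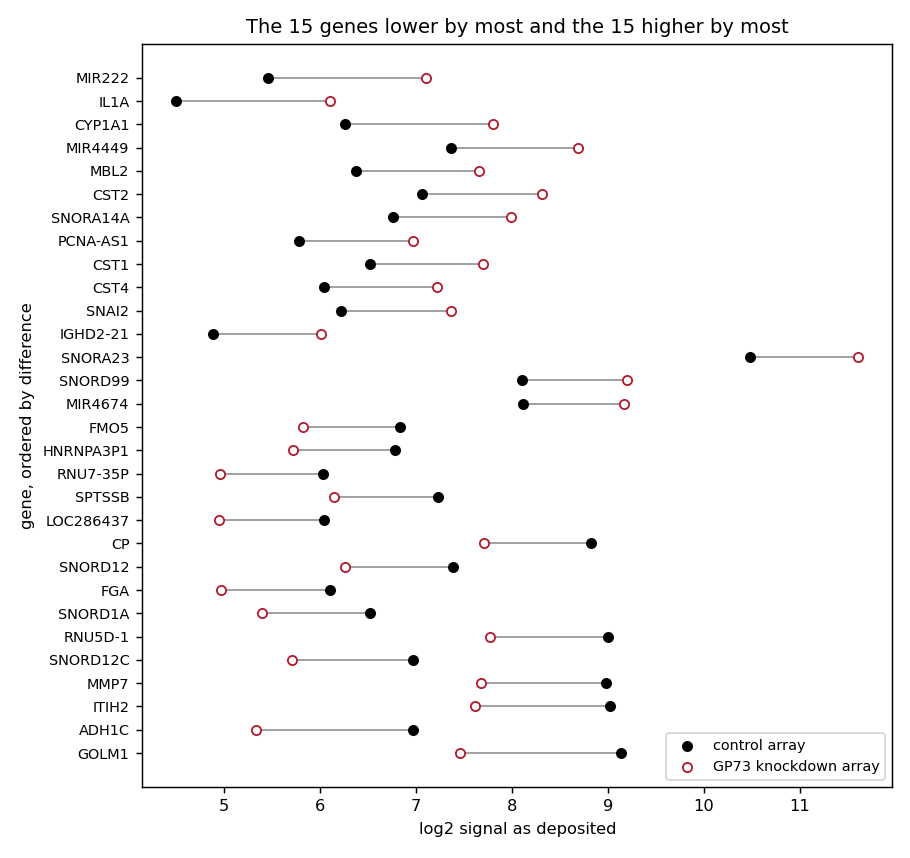
The 15 measured genes with the highest and the 15 with the lowest differences, ordered by difference, with the log2 signal as deposited (x axis) of the control array (filled points) and of the GP73 knockdown array (open points), 1 array each. GOLM1 moves from 9.13 to 7.46 and MIR222 from 5.46 to 7.11.

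Gene lists fixed before the data were examined were then compared, to see whether genes of a pathway or cell type differed together. The median difference of each list's measured members was placed among 10000 random lists of the same size and signal level, as a description of these 2 arrays. Of the 32 lists, 8 lay above the central 95% of their random lists and 1 lay below it. By chance 1.6 lists would be expected outside if the members of a list varied like randomly drawn genes. Members that vary together for any reason would put more lists outside, and this was not tested. The lists shared some members, and 29 genes stood in more than 1 of them. Differences also followed the signal level itself. With all 22413 genes put in 10 equal bins of mean signal, the median difference was 0.14 in bin 5 and -0.08 in bin 10, the highest.

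The lists of inflammatory, immediate early and mesenchymal genes had medians above those of their random lists. Among the inflammatory cytokines and NF-kB targets 12 of 16 measured members were higher, with a median of 0.29 at the 100.0th percentile of random lists; with the floor at the 75th percentile it was 0.10, at the 92.48th. Beside IL1A these included IL1B, interleukin-1 beta, at 0.62, TNFAIP3, an inhibitor of NF-kB signalling, at 0.54, and the kinase IRAK2 at 0.43. The leukocyte markers had a median of 0.47, at the 99.83th percentile, over 3 measured members, of which NKG7 and CD8A were below the floor in the control array and so counted as measured only through their higher signal in the knockdown array. Without a floor the median of that list was 0.20, at the 94.41th percentile. Among the immediate early genes 24 of 31 were higher, with a median of 0.18 at the 99.96th percentile. They included the mRNA-decay factor ZFP36 at 0.60, the AP-1 subunit FOSL1 at 0.60, the phosphatase DUSP1 at 0.59 and IER3 at 0.57. Among the mesenchymal genes 16 of 20 were higher, with a median of 0.15 at the 99.38th percentile. Beside SNAI2, the smooth muscle myosin light chain MYL9 was 2.04-fold higher, TAGLN stood at 0.45 and TGFBI at 0.35. TAGLN was below the floor in the control array, at 5.70, and counted as measured only through its higher signal in the knockdown array. Without a floor the median of the mesenchymal list was 0.16, at the 99.56th percentile. The list of epithelial junction and keratin genes had a median of 0.01, with 14 of 25 higher, including SPINT1 at 0.49 and CLDN2 at 0.34.

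The extracellular proteases and their inhibitors had a median of 0.18, at the 99.87th percentile, with 14 of 20 members higher. MMP7, at -1.30, went against the list's median, while MMP24 stood at 0.42, PLAT, the tissue plasminogen activator, at 0.38 and TIMP4 at 0.38. With the mean in place of the median, this list stood at 0.06 and the 92.77th percentile, and with the floor at the 75th percentile its median was 0.00, at the 79.27th. The list of YAP and TGF-beta targets had a median of 0.12, at the 98.78th percentile, with 18 of 24 members higher and 6 lower. F3, the coagulation starter tissue factor, was at 0.94, and SKIL at -0.68, ID1 at -0.66 and TGFBR2 at -0.57. Quantile normalisation put that list at the 94.17th percentile. Replication-dependent histone genes were higher in 11 of 11 measured members, with a median of 0.36 and the linker histone H1-4 at 0.74. Of the 44 members of the histone list, 19 had a row of their own. All 4 measured metallothioneins, which bind zinc and copper, were higher, with a median of 0.49, MT2A at 0.74 and MT1G at 0.68. MT1G was below the floor in the control array and counted as measured only through its higher signal in the knockdown array. Of the metallothioneins 9 had a row of their own, and without a floor the median was 0.44. Histone genes and metallothionein genes are families of paralogs, and the split of signal within each family is uncertain. Their members are therefore not separate observations.

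For genes of cell division, most measured members had negative differences, and the placing of their lists depended on the setting. Among the DNA replication and G1/S genes 28 of 40 measured members were lower, with a median of -0.15, at the 2.48th percentile of random lists. The clamp-loader subunit RFC3 stood at -0.70, the kinase CDK6 at -0.67, the primase PRIM1 at -0.59 and the polymerase POLA1 at -0.45. Among the mitosis genes 28 of 36 were lower, with a median of -0.16, at the 2.56th percentile, which is just inside the central 95%. The checkpoint gene MAD2L1 stood at -0.72, the mitotic kinesin CENPE at -0.68, ASPM at -0.59 and CDK1 at -0.53. No member of either list was at least 2-fold lower, and 3 of each were at least 1.5-fold lower. With the trend over signal level removed, the replication list stood at -0.08 and the 6.31th percentile and the mitosis list at -0.10 and the 4.28th, and with quantile normalisation both stood at the 5.36th, all inside the central 95%. The mitosis list lay outside in 6 of 9 alternative settings and the replication list in 4.

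The lists of Golgi, vesicle coat, unfolded protein response and ATF4 genes had medians below 0 that lay inside the central 95% of random lists of the same signal level. Of the Golgi structure and enzyme genes 27 of 35 measured members were lower and 1 was at least 1.5-fold lower, with a median of -0.09 at the 28.73th percentile. The lowest was MAN1A1, a Golgi mannosidase that trims N-glycans, at -0.91, followed by MAN1A2 at -0.50, GOLGA4 at -0.45 and GOLIM4 at -0.40. The mean of this list, -0.14, lay at the 1.98th percentile, outside the central 95%, so its placing depended on the summary. The COPI and COPII vesicle coats had a median of -0.17, at the 6.50th percentile, with 16 of 20 lower and ARF4 lowest at -0.36. The unfolded protein response genes had a median of -0.14, at the 6.17th percentile, with DNAJC3 at -0.52 and HYOU1 at -0.51. The ATF4 and amino acid stress genes had a median of -0.12, at the 4.97th percentile, with the serine synthesis enzymes PSAT1 at -0.76 and PHGDH at -0.53 and asparagine synthetase, ASNS, at -0.52.

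**Figure D3:**
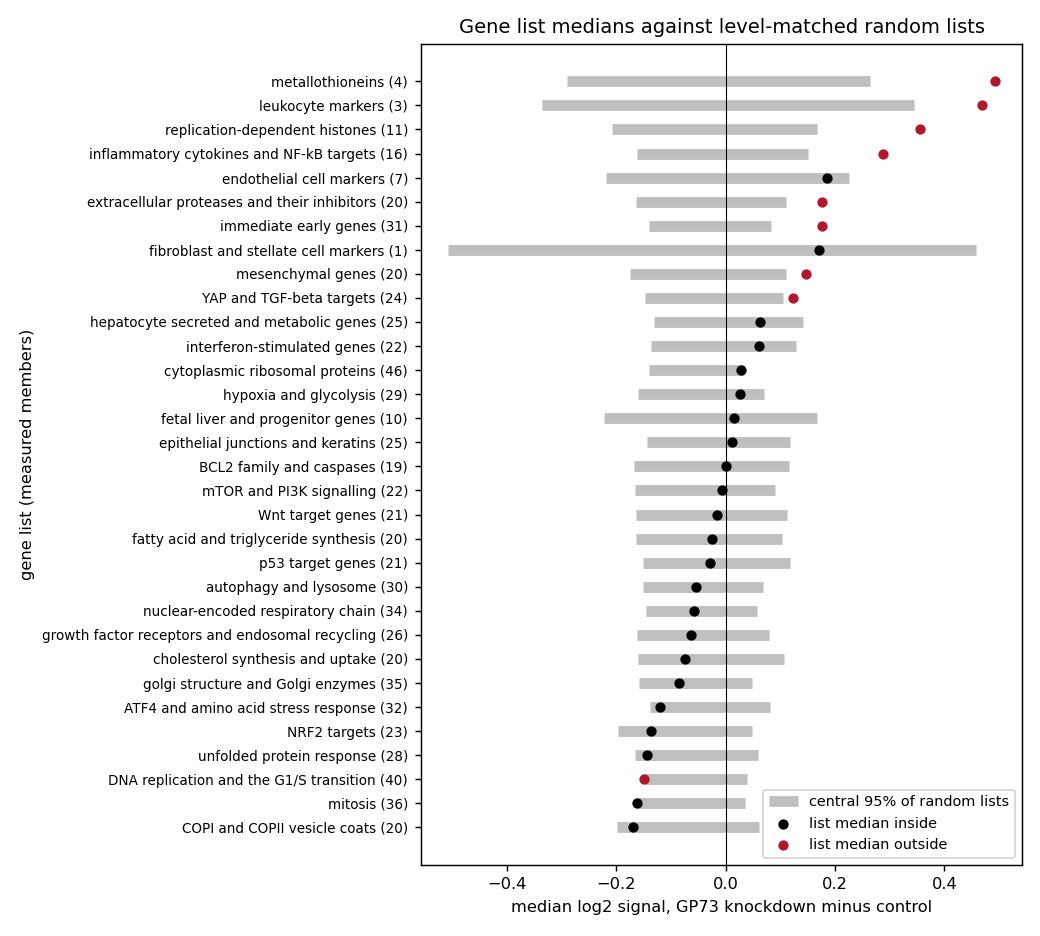
Median log2 difference, GP73 knockdown minus control (x axis), of each of 32 gene lists, with the number of measured members in brackets; grey bars span the central 95% of 10000 random lists of the same size and signal level, and red points lie outside them. The replication-dependent histones (0.36) and the inflammatory genes (0.29) lie to the right of their bars, and the DNA replication list (-0.15) lies at the left end of its bar.

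The hepatocyte secreted and metabolic genes held some of the largest differences in both directions and no common shift. Of 25 measured members 14 were higher and 11 lower, with CYP1A1 at 1.55 and ITIH2, FGA and CP at -1.40, -1.13 and -1.11. The median was 0.06, at the 79.17th percentile, and the mean was -0.06, of opposite sign. The fetal liver and progenitor genes had a median of 0.02, with ANPEP at 0.71, PEG10 at 0.62 and SOX4 at -0.40. Among the NRF2 targets 19 of 23 were lower, with a median of -0.14 at the 14.69th percentile, whereas HMOX1, the heme-degrading oxygenase, was 2.04-fold higher.

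Lists of growth and survival signalling lay inside the central 95%. The growth factor receptor and endosomal recycling genes had a median of -0.06, with TFRC at -0.38, ERBB3 at -0.36 and AXL at 0.34. The mTOR and PI3K genes had a median of -0.01, the Wnt targets -0.02, with RNF43 at -0.72, the p53 targets -0.03, with RRM2B at -0.50, and the BCL2 family and caspases 0.00, with XIAP at -0.49. With the floor at the 75th percentile the BCL2 list stood at -0.27 and the 2.07th percentile, outside the central 95%. Among genes often studied in liver cancer growth, and chosen here after their values were seen, EGFR stood at 0.25, RAB11A at -0.31, MTOR at -0.21, CCND1 at 0.20 and CDH1 at 0.24. The medians of the mTOR, Wnt, BCL2, fatty acid and autophagy lists changed sign under another scaling of the arrays, so no direction is given for them. The metabolic lists also lay inside: cholesterol synthesis and uptake at -0.08, fatty acid and triglyceride synthesis at -0.03 with ME1 at -0.65, hypoxia and glycolysis at 0.03, the respiratory chain at -0.06, and autophagy and lysosome at -0.05. The interferon-stimulated genes had a median of 0.06, with IFI6 at 0.54 and no member at least 1.5-fold different. The cytoplasmic ribosomal proteins had a median of 0.03, at the 96.55th percentile, but lay outside in 3 of 9 alternative settings, at 0.08 and the 97.55th percentile with the trend removed and 0.08 and the 99.72th with the higher floor. Each of these placings describes 1 array against 1 array, and a list inside the central 95% was not shown to be unaffected.

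Few fibroblast and leukocyte markers were measured. Endothelial markers were measured about as often as the listed hepatocyte genes, of which 25 of 57 were. The floor was the median of the higher signal over all genes, so a marker below it was not shown to be absent. Of 15 fibroblast and stellate cell markers 1 was measured, COL1A1, at 0.17. Of 15 endothelial markers 7 were measured, with a median of 0.19, inside the central 95%, and PECAM1 at -0.72. PECAM1 was below the floor in the knockdown array, at 5.26, so the size of its difference is uncertain. Of 16 leukocyte markers 3 were measured, CD68 at 0.49, NKG7 at 0.47 and CD8A at 0.16. CD68 codes for a lysosomal protein and had a log2 signal of 9.25 in the control array.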

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

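Rows of the array that carry no gene symbol were outside every comparison of the report, and some differed by more than any measured named gene. Of 7928 such transcript clusters above the floor 82 were at least 2-fold higher in the knockdown array and 46 at least 2-fold lower, against 18 and 15 of 11207 named genes. Rows whose ID is not that of a transcript cluster were counted apart, whether or not they carry a symbol. Of 2132 such rows above the floor 10 were at least 2-fold higher and 35 lower, and what they measure was not examined. The transcript clusters with the highest differences were TC17000665.hg.1, with log2 signals of 4.04 in the control and 7.95 in the knockdown array, a difference of 3.91, and TC04000772.hg.1, from 4.99 to 8.20, a difference of 3.21; both were below the floor of 5.84 in the control array, so the size of these differences is uncertain. Those with the lowest were TC03002425.hg.1 at -2.03 and TC04002793.hg.1 at -1.72. The higher ones are given because they show a signal above the control array in data that the comparisons did not use, and the lower ones are set beside them. The annotation used here names no gene for them, and no explanation was tested.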

How the results depend on the processing

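The restrictions to protein-coding genes were chosen after seeing the data. The direction and size of the GOLM1 difference changed by less than the SD between rows of a gene under all 4 alternatives run for it, and the same held for the other 145 named genes in 580 of 580 recomputed values. The mean over rows could change only H2BC11 and IER3, the named genes with further rows. The scalings shift genes of similar signal alike, so these values do not measure the error of a single gene's difference. Counts of genes depended on the threshold and the floor. Against 18 genes at least 2-fold higher, 121 passed at 1.5-fold and 2 at 3-fold, and 9 were protein-coding. Against 15 at least 2-fold lower, 174 passed at 1.5-fold and 2 at 3-fold, 23 passed without a floor, 9 with the floor at the 75th percentile, 23 with the robust z of 4, and 8 were protein-coding. These changes follow from the construction of the alternatives, which alter the threshold or the genes counted. Quantile normalisation and trend removal each kept all 18 and all 15 genes of the main setting. The number of lists outside the central 95% was 9 and ran from 7 to 12 over the 9 alternatives. The immediate early, mesenchymal, metallothionein and histone lists lay outside in all 9, the inflammatory list in 8, the leukocyte list in 8, the protease list in 6, the YAP and TGF-beta list in 6 and the DNA replication list in 4. The leukocyte list lay inside only without a floor, at the 94.41th percentile. Its members NKG7 and CD8A passed the main floor only through the knockdown array, so its placing depends on the floor. Of the lists inside in the main setting, mitosis lay outside in 6, the ribosomal proteins in 3, the ATF4 genes in 2, and the Golgi, vesicle coat, unfolded protein response and BCL2 lists in 1 each. With the higher floor the inflammatory list fell to the 92.48th percentile and the protease list to the 79.27th; the cause was not tested. Of 287 list values recomputed, medians or, in 1 alternative, means, 22 moved by more than the SD of their random lists, no list outside the central 95% changed sign, and 5 lists inside it changed sign under a scaling. No paired analysis was possible because each group is 1 array, no replicate could be left out, and other rows for GOLM1 gave no value because it has 1 row. Signal over background limits the genes that were below the floor in 1 array, whose differences are uncertain in size.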

Other observations

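Kinds of gene differed in how far they spread. Small nucleolar RNAs, which guide modification of ribosomal and spliceosomal RNA, made up 104 of the measured genes and 6.73% of them passed 2-fold, 4 higher and 3 lower, against 0.17% of protein-coding genes. Beside SNORD12 and SNORD12C the related SNORD12B was lower, at -0.49, and below the floor in the knockdown array, at 5.78. MIR221, which is processed from the same primary transcript as MIR222, was higher by 0.58. Of the other fibrinogen chains FGB was at 5.13 in the control and 3.93 in the knockdown array, and FGG at 2.85 and 2.38, both below the floor. These genes were picked after their values were seen.

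The tests of the small RNAs and of CYP1A1 below were chosen after the result they concern had been seen. The pseudogene test was prompted by differences already seen, and its correlation had not been computed when it was chosen.

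The gene lists outside the central 95% were weighed against the trend of the difference with signal level, in which weakly expressed genes were higher and strongly expressed genes lower in the knockdown array. With that trend removed, 7 of the 9 lists stayed outside on the same side. The random lists were already matched on signal level in the main setting. Removing the trend could therefore only show what was left of it within a bin, and the placing of the 7 lists did not rest on that part. The exceptions were the DNA replication list, from -0.15 to -0.08, and the YAP and TGF-beta list, from 0.12 to 0.09, whose medians came closer to 0 and for which the trend stays open. Whether 2 single arrays of the same cells would differ as much cannot be told apart from the knockdown, because each group has 1 array. Gene length and GC content were not tested.

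Pseudogene rows such as HNRNPA3P1 at -1.06, HNRNPA3P5 at -0.83 and FABP5P1 at 0.87 were among the larger differences, and a candidate explanation is that their probes read transcripts of the parent gene. Across 135 protein-coding parents with 182 measured pseudogenes, the difference of the parent and the mean difference of its pseudogene rows correlated with a Pearson r of 0.706 and a Spearman rho of 0.74, where the central 95% of shuffled pairings ended at a Pearson r of 0.160. This relation is across genes, which are not independent replicates. The pairs did not include HNRNPA3, whose row carries several symbols, so its pseudogenes were not covered and the explanation stays open for them. Parent and pseudogene need not match in size. FABP5 itself stood at 0.24, with log2 signals of 5.89 and 6.14 in the control and knockdown arrays, against 7.65 and 8.53 for FABP5P1. RANP1 stood at -0.98 and its parent RAN at -0.38. The correlation does not account for these larger differences of the pseudogene rows. These genes were picked after their values were seen. Regulation of the pseudogenes together with their parents was not tested.

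For the small nucleolar RNAs, a different yield shared by all small RNAs of a preparation would move them together. Of the 104 measured 48.1% were higher and the rest lower or equal, which argues against a difference in yield shared by the small nucleolar RNAs. A difference in yield that acts on only some of them was not tested. Other small RNAs leaned higher, with 59.7% of 263 microRNA genes and 61.9% of 21 small nuclear RNA genes, against 46.6% of protein-coding genes. A smaller difference in yield of those kinds was therefore not excluded. A candidate explanation that stays open is that rows of short RNAs are noisier. Measured microRNA genes, 263 in number, had a robust SD of the difference of 0.319, above 0.291, the upper end of the central 95% of protein-coding sets of the same size and level, and small nucleolar RNAs had one of 0.40. An effect of the knockdown on single small RNAs was not excluded.

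CYP1A1 is a classical target of the aryl hydrocarbon receptor, and one hypothesis was that this receptor was more active in the knockdown cells. The median of 10 other measured targets was 0.057, at the 86.48th percentile of random lists, with 5 of 10 higher. The highest were CYP1B1 at 0.25 and TIPARP at 0.24, and the lowest were HES1 at -0.35 and TXNRD1 at -0.19. The list lay inside the central 95% with members on both sides of 0, which does not decide the question, and the hypothesis stays open.

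Among the measured genes 190, or 1.70%, had exactly the same deposited value in both arrays, while 16 others differed by less than 0.001, and of all 70523 deposited signals 4359 were the same in both.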
